A study of Mus musculus with 8 samples.

How the data were processed

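The series compared soleus muscle of 4 male Ts65Dn mice with that of 4 male wild-type mice from the colony, all aged 5 months, with 1 array per mouse. Per the labels' protocols, total RNA was extracted with a column kit and biotinylated cDNA was made with a whole-transcript amplification system. Per the submitters' processing notes, the authors made gene-level values with Affymetrix Expression Console 1.1 and RMA, which corrects background, normalizes probes between arrays and summarises each probe set. The deposited values are log2 values, read as such from their range, since the scale is not stated in words. Higher values are brighter and genes are not centred. The genome build and annotation release are not given in the sources used here. Scanner files were not used here. The column medians of the deposited values were 4.24, 4.26, 4.29 and 4.23 for Ts65Dn replicates 1 to 4 and 4.39, 4.52, 4.56 and 4.37 for wild-type replicates 1 to 4.

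The value table holds 35556 probe sets, of which 21789 have 1 gene symbol in the platform annotation, 1621 several and 12146 none. Symbols were updated through the Entrez identifier with the RefSeq gene table of assembly GRCm38.p6 for 21698 probe sets, and 91 kept the symbol of the array annotation. Probe sets with several symbols or none were left out of the gene tests. For the 999 genes with several probe sets, the one with the highest mean over all arrays was used, which left 19938 genes. Because the authors' build is not named, the RefSeq table was used for names and gene order and no coordinates are given. The trisomic segments were taken in gene order, from Mrpl39 to the distal end of MMU16 and from the centromere through Pde10a on MMU17. They hold 293 and 184 annotated genes, of which 129 and 31 were measured.

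Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 19938 genes and a threshold of 0.05. No covariate or block was used. For each trisomic segment, the mean log2 value per array was compared by an exact two-sided permutation test over all 70 splits of the arrays, whose smallest p is 0.0286. Each of the 28 gene lists fixed before the data were examined and the 2 segments was tested with camera at a preset correlation of 0.01, where 5 or more members were measured. Camera compares a list with all other genes, so that a list called higher is higher relative to them. Camera with an estimated correlation and fry were run beside it. The lists hold 765 genes, of which 705 were measured, and the others were not analysed here. Level-matched values subtract, in each array, the median deviation of the 100 genes outside the segments nearest in mean level. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the plots.

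Genes named in the text follow a rule fixed before the data were examined. They are the 12 trisomic genes with the smallest p, the 12 higher and 12 lower called genes outside the segments with the largest fold change, up to 4 members per list with the smallest p, and 15 genes fixed by name, among them App, Sod1, Dyrk1a and the myosin heavy chains. Predicted genes, receptor families and small RNAs were counted and not named by fold change. Other genes are said to have been chosen after their values were seen.

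The gene and list tests were tested on simulated data made on the 8 arrays for the comparison of Ts65Dn with wild type over 19938 genes, with 200 changed genes. Of genes changed by 1 on the log2 scale 76% were recovered, and of those changed by 2, 97%. False calls made up 4.95% of all calls, and 0 genes were called with none changed. Both of the 2 lists moved in the simulation were called, and 1 unmoved list was called. Genes were drawn independently of each other, without correlation within lists and without the difference in range between the real arrays. These rates therefore hold for that setting and do not give the error rates of the real comparison.

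Alternatives were another quantile normalization, centring on the array median, a filter on dim genes, the mean of all probe sets of a gene, the replicate number as a block, array weights, an intensity trend with robust estimation, another threshold, adjustment over the genes outside the segments, and leaving out each array. Hand-written segment lists, the mean over members, other list tests and lists without trisomic genes were tried as well. Cyclic loess, level matching, leaving out wild-type arrays 2 and 3 together and adjusting all probe sets together were added after the data were seen.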

Results

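Gene expression was measured in the soleus, a slow postural muscle of the lower leg, of male mice aged 5 months. Ts65Dn mice are a model of Down syndrome. They carry an extra marker chromosome, so that the distal end of mouse chromosome 16 (MMU16) and the centromeric end of chromosome 17 (MMU17) are present in 3 copies. The 4 Ts65Dn mice and 4 wild-type colony controls gave 1 array each. Muscles were taken in the basal state. Values are log2 RMA values of Affymetrix Mouse Gene 1.0 ST arrays, and 19938 genes were compared. With 4 arrays in each group, the number of arrays limits the precision.

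The arrays differed between the groups before any gene was considered. The array median was 4.26 ± 0.02 (SD, n = 4) in Ts65Dn and 4.46 ± 0.09 (SD, n = 4) in wild type, and no array of one group lay within the range of the other (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). The interquartile range was 3.05 ± 0.05 (SD, n = 4) against 2.80 ± 0.15 (SD, n = 4), with the same exact permutation p of 0.0286. Wild-type arrays 2 and 3 stood apart, with interquartile ranges of 2.74 and 2.62. Genes outside the trisomic segments had a median log2 fold change of -0.22 at a mean level of 5 or less and of 0.31 between 7 and 9. The median over all genes was -0.10, and 0.10 with each array centred on its median. Values relative to the 100 genes outside the segments that lay nearest in mean level, called level-matched values, are therefore also given for the segments, and for called genes whose fold change they moved by over 1.5 times. Values without wild-type arrays 2 and 3 are given for called genes by the same rule.

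**Figure D1:**
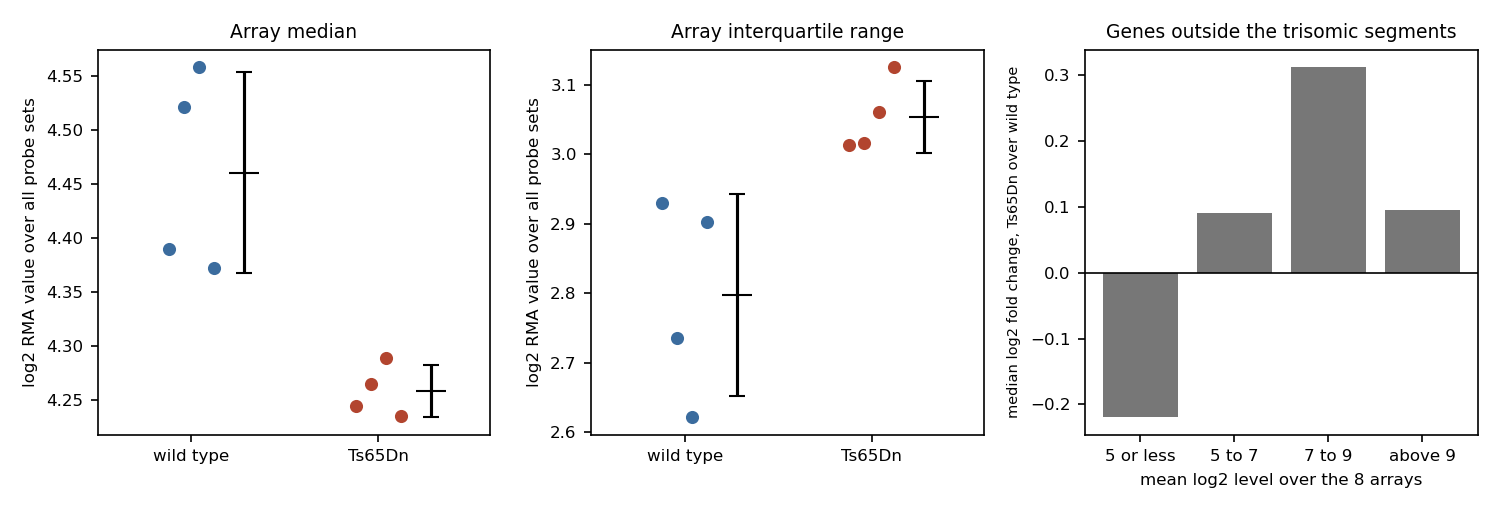
Median and interquartile range of the log2 RMA values of each array, as 1 point per array with the mean and SD of 4 arrays beside them, and the median log2 fold change of genes outside the trisomic segments by mean log2 level. The Ts65Dn medians lie between 4.23 and 4.29 and the wild-type medians between 4.37 and 4.56, and dim genes have a median fold change of -0.22.

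The first comparison asked whether genes carried in 3 copies were expressed at a higher level in Ts65Dn muscle. Among the genes of the MMU16 segment, App, the precursor of amyloid beta, was at 8.40 ± 0.21 in Ts65Dn and 7.09 ± 0.46 in wild type (log2, SD, n = 4), a log2 fold change of 1.31 with a limma adjusted p of 0.0456. The interferon receptor chain Ifnar2 rose by 1.04 on the log2 scale, the endocytic scaffold Itsn1 by 0.88, the transcription factor Sim2 by 0.86, and the kinase Dyrk1a by 1.22. Rcan1, an inhibitor of calcineurin, rose by 0.84 (limma adjusted p = 0.0493). On MMU17, Tiam2 rose by 1.68 and Scaf8 by 1.30.

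Of the 129 measured MMU16 genes, 21 were called higher and 3 lower, and of the 31 measured MMU17 genes 6 were called higher and 0 lower. Adjusted over the list alone, 34 MMU16 genes were higher and 17 lower, and 11 MMU17 genes were higher and 4 lower. Trisomic genes made up 27 of the 462 genes called higher. That was 16.9% of the 160 trisomic genes against 2.20% of the 19778 others, an odds ratio of 9.02 (Fisher's exact test, two-sided, p = 5.73e-16, across genes, which are not independent replicates). Morc3 rose by 1.65, Vps26c by 1.23, Ttc3 by 1.15, C2cd2 by 1.15, Rwdd2b by 0.77 and Cct8, a subunit of a cytosolic chaperonin, by 0.64.

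The mean over all MMU16 trisomic genes was 5.23 ± 0.02 in Ts65Dn and 5.08 ± 0.01 in wild type (log2, SD, n = 4), a difference of 0.15 (exact two-sided permutation p = 0.0286, all 4 Ts65Dn arrays higher). The median log2 fold change over these genes was -0.03, so that the median and the mean differed in sign. Leaving out single arrays moved this median between -0.0720 (without wild-type array 1) and 0.0161 (without Ts65Dn array 3). The level-matched median over all 129 genes was 0.07, and 84 level-matched values were positive. The 68 genes at or below the median level of all genes had a median of -0.20, beside -0.21 for genes outside the segments at that level. Their level-matched median was 0.01. The 61 genes above that level had a median of 0.53, and 53 of these were positive. At that level the median was 0.11 for genes outside the segments and 0.21 for the MMU16 genes outside the segment. For comparison, 3 copies over 2 correspond to 0.58 on the log2 scale. The level-matched median of the 61 genes was 0.37, and 48 of their level-matched values were positive.

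For MMU17, the mean over all 31 genes was 5.68 ± 0.05 against 5.46 ± 0.04 (log2, SD, n = 4), a difference of 0.22 (exact two-sided permutation p = 0.0286), with a median fold change of 0.04, which was 0.0108 without Ts65Dn array 3 and 0.18 and 0.16 without wild-type arrays 2 and 3 in turn. The 19 genes above the median level had a median of 0.48 and a level-matched median of 0.20. Level-matched means of the genes above the median level differed by 0.41 for MMU16 and 0.39 for MMU17 (exact permutation p = 0.0286 for each). Most chromosomes outside the segments gave the same exact permutation p, with differences of at most 0.17. The p therefore does not set the segments apart. Their differences were the largest, but they are means over 61 and 19 genes, against 252 to 898 genes per chromosome. Gene sets of equal size were not drawn, so how far size alone sets the segments apart was not tested. With wild-type arrays 2 and 3 left out, an alternative added after the arrays were seen, the exact permutation p of the mean over all genes of a segment was 0.0667 for both, the smallest that 6 arrays can give, and the median for MMU16 was 0.03.

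Not all genes in 3 copies were called higher. Sod1, the cytosolic superoxide dismutase, was at 11.57 ± 0.04 in Ts65Dn and 11.50 ± 0.16 in wild type (log2, SD, n = 4; limma adjusted p = 0.689). The ATP synthase subunit Atp5j had a log2 fold change of 0.08 (limma adjusted p = 0.623) and Atp5o one of 0.26 (limma adjusted p = 0.134). Over the alternatives tried, the log2 fold change reached 0.27 for Sod1 and 0.28 for Atp5j, and neither passed in any. Without wild-type arrays 2 and 3 it was 0.20 for Sod1. Sod1, Atp5j and Atp5o lay above a level of 9, where MMU16 trisomic genes had a median of 0.26, beside 0.77 between 7 and 9. Ets2 (1.09), Ifnar1 (0.75), Cbr1 (0.53) and Runx1 (0.41) had positive log2 fold changes that did not pass, with limma adjusted p-values of 0.0569, 0.105, 0.0800 and 0.0690. Dyrk1a has 2 probe sets, with log2 fold changes of 1.22 and -0.43, and 0.40 for their mean. Scaf8 was at 0.87 without wild-type arrays 2 and 3.

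**Figure D2:**
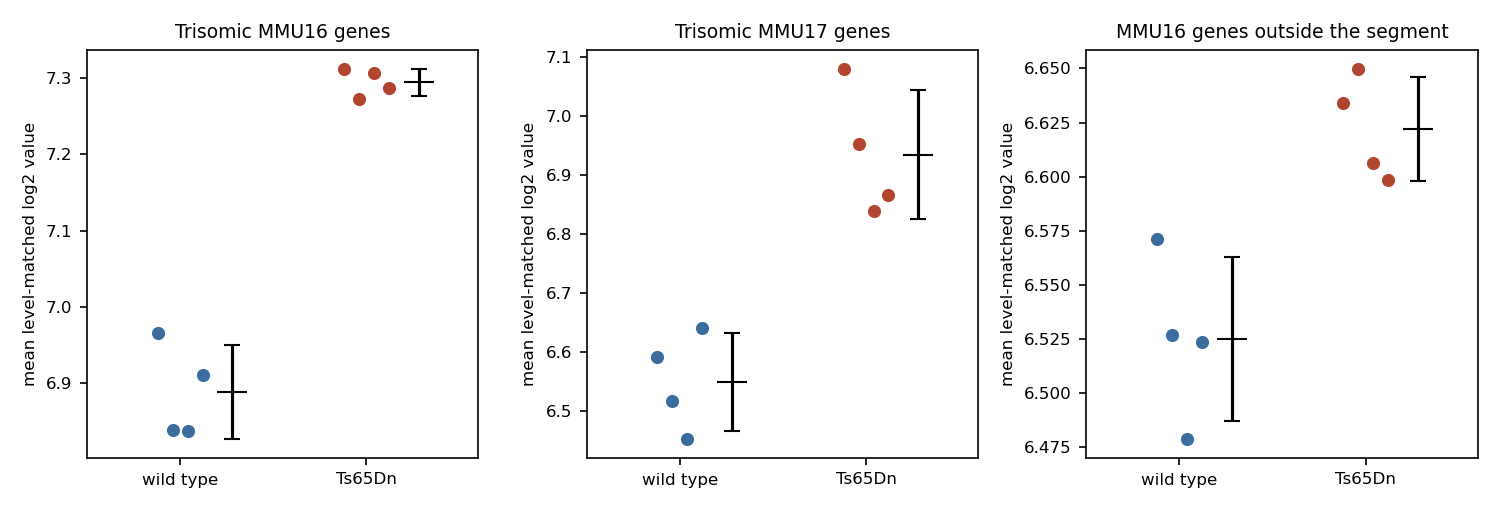
Mean level-matched log2 value per array of the trisomic MMU16 genes, the trisomic MMU17 genes and the MMU16 genes outside the segment, each for genes above the median level, as 1 point per array with the mean and SD of 4 arrays. All Ts65Dn arrays lie above all wild-type arrays in each panel, with differences of 0.41, 0.39 and 0.10, and each panel has its own axis.

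Along MMU16, the 20 trisomic genes above the median level nearest to the segment boundary had a level-matched median of 0.34, and the 20 genes on the diploid side one of 0.23. On MMU17 these values were 0.20, over the 19 trisomic genes, and 0.06. Positive values were held by 15 trisomic and 16 diploid genes on MMU16, so their number did not step up at that boundary, and by 13 and 12 on MMU17. The MMU16 genes outside the segment differed by 0.10 between the groups in the mean of level-matched values (exact permutation p = 0.0286), and the MMU17 genes outside the segment by -0.02 (exact permutation p = 0.343).

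**Figure D3:**
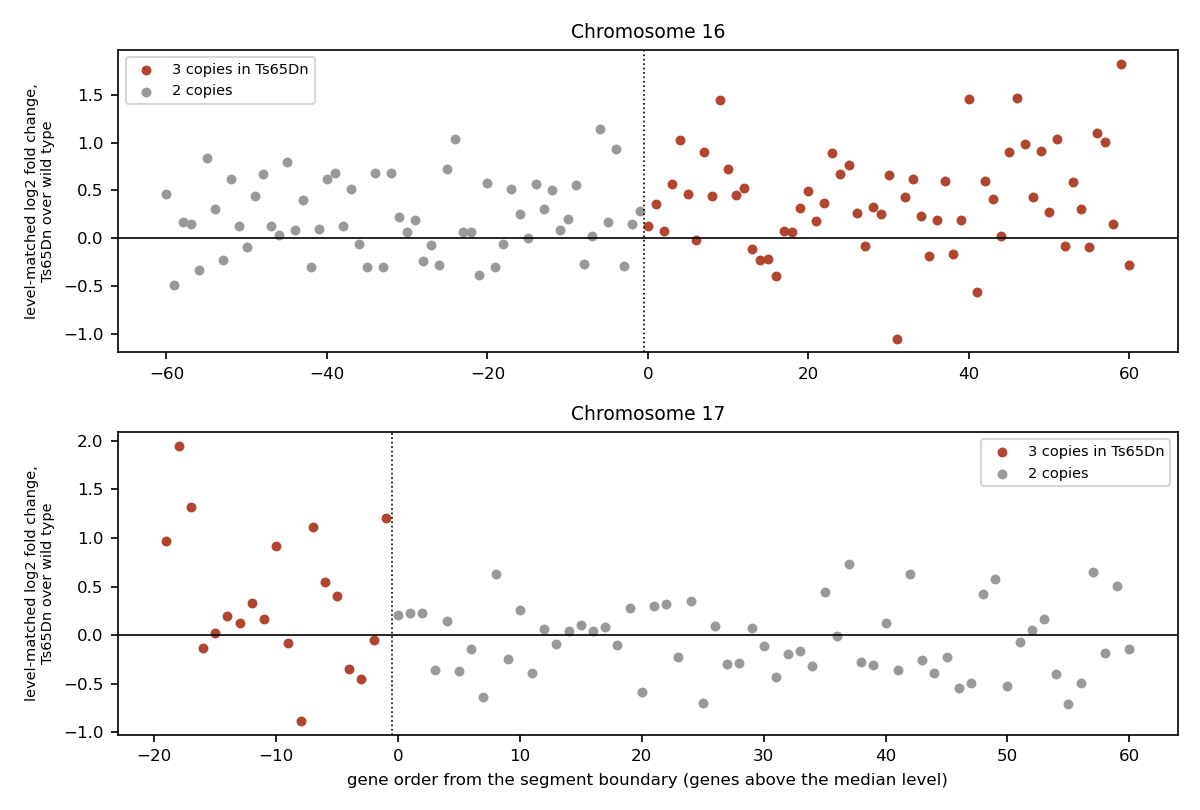
Level-matched log2 fold change of genes above the median level in their order from the boundary of the trisomic segment on chromosomes 16 and 17, coloured by copy number, with 1 point per gene. Trisomic genes within 20 of the boundary have medians of 0.34 and 0.20, against 0.23 and 0.06 on the diploid side. On chromosome 16, 15 of these trisomic and 16 of the diploid genes are positive, and on chromosome 17, 13 and 12.

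**Figure D4:**
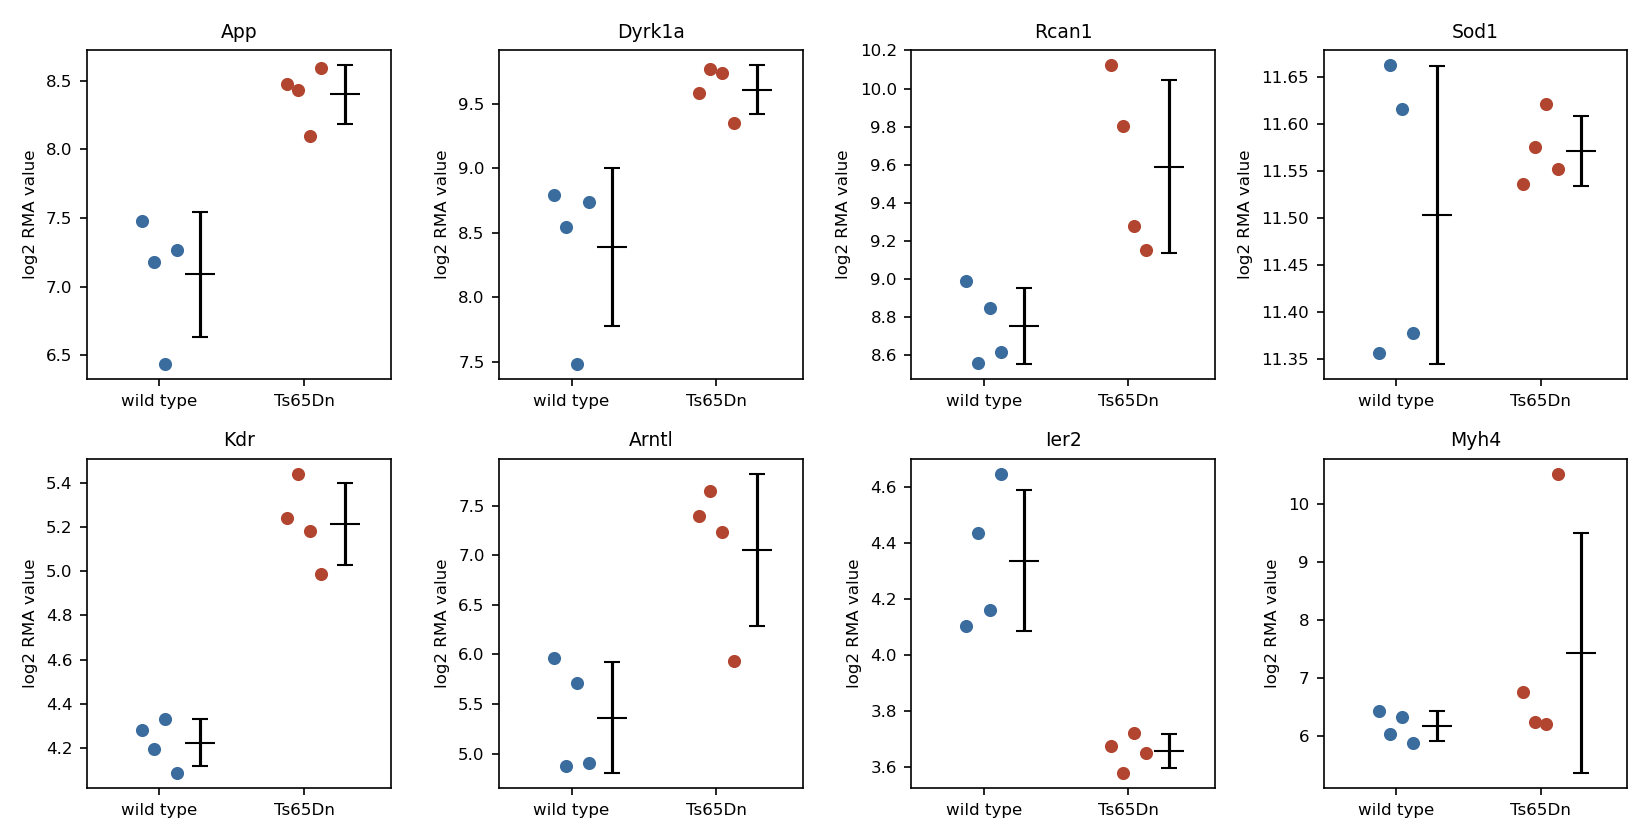
Log2 RMA values of 8 named genes in each array, as 1 point per array with the mean and SD of 4 arrays per group. App, Dyrk1a, Rcan1 and Kdr are higher and Ier2 is lower in every Ts65Dn array, Sod1 overlaps between the groups, Arntl is higher in 3 of the 4 Ts65Dn arrays, and Myh4 reaches 10.5 in 1 Ts65Dn array.

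The second comparison asked which other genes differed between Ts65Dn and wild-type soleus. Outside the trisomic segments, the largest increases among named genes were those of Cd68, a lysosomal protein of macrophages (2.39), Tecrl (2.03), Osbpl8 (1.92) and the matrix protein Postn (1.87), all as log2 fold changes. Arntl, the clock transcription factor also called Bmal1, was at 7.05 ± 0.77 against 5.36 ± 0.56 (log2, SD, n = 4), a log2 fold change of 1.69 with 3 of 4 Ts65Dn arrays above the wild-type range. Zdhhc21 rose by 1.62 and Myl6b, a myosin light chain, by 1.48. Among named genes the decreases were smaller than the increases. Hbq1b fell by 0.97, Krtap5-3 by 0.95, Prss53 by 0.89, Rln3 by 0.88 and Ldlrad1 by 0.85. Dlk1 fell by 0.83. Without wild-type arrays 2 and 3 the log2 fold change was -0.52 for Krtap5-3 and -0.54 for Dlk1.

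In all, 1049 genes passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, 462 higher and 587 lower in Ts65Dn, of which 1019 lay outside the segments and 94 of those were predicted, receptor or small RNA genes. The smallest adjusted p was 0.0449, so that every call lay close to the threshold, and 6948 genes had an unadjusted p under 0.05 against 996.9 by chance. The count was 1 with the arrays quantile normalized once more. With all 35556 probe sets adjusted together 1 probe set without a single gene name passed, and those of the called genes had adjusted p-values from 0.0793 to 0.0862. The limma count was 0 without Ts65Dn array 1, 3 or 4 or wild-type array 2, and 1 without Ts65Dn array 2 or wild-type array 3, with 5271 to 6050 genes at an unadjusted p under 0.05, while it was 2865 and 2422 without wild-type arrays 1 and 4. It was 1 without both wild-type arrays 2 and 3. Centring each array on its median gave 951 higher and 57 lower calls, cyclic loess 117 and 18, and level matching 86 and 23, so the split between higher and lower calls depended on the scaling.

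Of the remaining genes named for their size, Lpp (1.85), Myo9a (1.74), Lclat1 (1.56), E2f3 (1.48) and Taf2 (1.48) were higher, and Aldh3b3 (-0.84), Rasef (-0.84), Thap8 (-0.84), Nol4 (-0.83), B9d1os (-0.83) and Amigo3 (-0.80) were lower, all as log2 fold changes. Over the 24 genes named in this way the limma adjusted p-values ran from 0.0449 to 0.0498. Probe sets of 1 gene disagreed in sign for Lpp, whose 3 probe sets ranged from -0.38 to 1.85, and for E2f3, from -0.29 to 1.48. With the mean of all probe sets, the log2 fold change was 0.55 for Lpp, 0.60 for E2f3, 0.94 for Myo9a, whose 13 probe sets ranged from 0.07 to 1.86, and -0.50 for Rasef. Without wild-type arrays 2 and 3 it was 0.82 for Taf2, 0.78 for E2f3 and -0.50 for Aldh3b3. The level-matched values were -0.54 for Thap8 and -0.52 for B9d1os.

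Genes of the contractile apparatus were described by 3 lists. In the list of sarcomere scaffold and dystrophin complex genes, 22 of 24 measured members had a positive fold change and 3 were called higher, with 6 adjusted over the list alone. These were the M-band proteins Myom2 (1.09) and Myom3 (0.94, level-matched 0.60) and the actin-binding protein Xirp2 (0.58). The list was called higher by camera with a preset correlation (limma adjusted p = 9.95e-06), and had an adjusted p of 0.348 with an estimated correlation. Of 14 fast-fibre genes 0 were called by limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, with a camera adjusted p of 0.0426 and an adjusted p of 0.348 with an estimated correlation. The fast-fibre call was lost with quantile normalization (adjusted p = 0.125), level matching (0.340), both wild-type arrays 2 and 3 left out (0.1001), and without Ts65Dn array 1 (0.0906) or 4 (0.0632) or wild-type array 3 (0.0732) or 4 (0.0646). It was also lost with the replicate block (0.0547), array weights (0.0657) and genes above the median level (0.626). The myosin heavy chains Myh2 and Myh1 had log2 fold changes of 0.12 and 0.26. Of 13 slow-fibre genes 0 were called by limma over all genes and 1 over the list alone, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.196), and Myh7, the slow myosin heavy chain, was at 10.52 ± 0.10 against 10.26 ± 0.35 (log2, SD, n = 4; limma adjusted p = 0.282).

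In the list of calcineurin and NFAT genes, 4 of 21 were called higher, with 6 adjusted over the list alone. They were Dyrk1a and Rcan1, which lie in the trisomic segment, the kinase Gsk3b (0.86, level-matched 0.57) and the muscle transcription factor Mef2a (0.68). Without wild-type arrays 2 and 3 the values were 0.55 for Gsk3b and 0.42 for Mef2a. The camera adjusted p was 0.000416, and the adjusted p was 0.348 with an estimated correlation. Of 19 genes of excitation-contraction coupling 0 were called by limma, over all genes or the list alone, with 2 at an unadjusted p under 0.05, and 17 had a positive fold change (camera adjusted p = 0.00943, adjusted p = 0.292 with an estimated correlation). The camera adjusted p was 0.914 with level matching and 0.357 with quantile normalization for this list, and 0.0845 with level matching for the calcineurin list.

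Energy metabolism showed few called genes. Of 31 genes of glucose handling 2 were called higher, as over the list alone: Tbc1d1 (0.95), which acts in glucose transporter traffic, and the insulin receptor substrate Irs1 (1.03). The camera adjusted p was 0.000416, with an adjusted p of 0.367 with an estimated correlation. Of 33 fatty acid genes 1 was called, Pdk4 (0.62), an inhibitor of pyruvate dehydrogenase, with 0 over the list alone (camera adjusted p = 0.0155, adjusted p = 0.486 with an estimated correlation). The fatty acid call was lost with level matching (adjusted p = 0.915), quantile normalization (0.580), and without wild-type array 2 (0.0620), array 3 (0.0742) or both (0.890), where the median turned from 0.08 to -0.07. It was also lost with array weights (0.0894), cyclic loess, and among genes above the median level (0.696). The glucose call was lost with level matching (0.154) and without both wild-type arrays 2 and 3 (0.0649), where the median was 0.03 against 0.22. Cyclic loess and genes above the median level (0.247) lost the glucose call too. Of 72 nuclear-encoded respiratory chain and ATP synthase genes 0 were called by limma, over all genes or the list alone, with 2 at an unadjusted p under 0.05. The median was -0.03, and 51 had a negative fold change (camera adjusted p = 0.702). The direction of that list turned with the scaling: it was lower with cyclic loess (median -0.11, camera adjusted p = 8.12e-05) and higher with each array centred on its median (median 0.17, camera adjusted p = 0.0229), and over all alternatives the adjusted p ran from 8.12e-05 to 0.955. Of 18 citric acid cycle genes 0 were called by limma, over all genes or the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.0518). That list passed, as higher, with each array centred on its median (0.0198), without Ts65Dn array 4 (0.0353) and without wild-type array 1 (0.0188) or 4 (0.0225), and its median turned from 0.08 to -0.06 without wild-type arrays 2 and 3 (0.644).

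Protein handling and stress lists had positive medians. Of 31 proteasome genes 28 had a positive fold change and 2 were called higher, as over the list alone, Psmd11 (0.58, level-matched 0.33) and Psmc4 (0.51, level-matched 0.25), with a camera adjusted p of 0.000136 and an adjusted p of 0.348 with an estimated correlation. Of 24 heat shock and unfolded protein genes 0 were called by limma over all genes, and 2 higher and 1 lower over the list alone, with 12 at an unadjusted p under 0.05 (camera adjusted p = 0.000248, adjusted p = 0.348 with an estimated correlation). Of 29 antioxidant genes 2 were called higher, as over the list alone, Sesn1, at 7.83 ± 0.43 against 6.72 ± 0.27 (log2, SD, n = 4), and catalase, Cat (0.52), with a camera adjusted p of 0.0195 and an adjusted p of 0.367 with an estimated correlation. Of 20 denervation and atrophy genes 1 was called, Eda2r (1.30), and 6 were higher and 1 lower over the list alone (camera adjusted p = 0.00113, adjusted p = 0.196 with an estimated correlation). Its adjusted p by fry, which tests the list on its own, was 0.00612. With level matching all 4 lists lost the camera call, with adjusted p-values of 0.349 for the proteasome, where the median was 0.05 against 0.16, 0.0845 for heat shock, 0.700 for antioxidant and 0.253 for denervation genes. The antioxidant call was also lost with quantile normalization (0.261), without wild-type array 2 (0.0689), and without wild-type arrays 2 and 3 (0.528), where the median was 0.05 against 0.14. Array weights (0.0657), cyclic loess and genes above the median level (0.520) lost it too.

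The immediate early genes were the list called lower. Of 20 genes 4 were called lower, with 6 over the list alone, and 17 had a negative fold change. The 4 were Ier2, Nr4a2, Egr3 and Fosb, which fell by 0.68, 0.61, 0.56 and 0.50 on the log2 scale. Their level-matched values were -0.40, -0.34, -0.61 and -0.19, and Egr3 was at -0.33 without wild-type arrays 2 and 3. The camera adjusted p was 0.0495, with an adjusted p of 0.429 with an estimated correlation, and the mean of the list per array differed by -0.22 (exact two-sided permutation p = 0.114). With trisomic genes left out of the lists and the background, the camera adjusted p was 0.0557 for this list. The call was lost without Ts65Dn array 2 (0.130), 3 (0.108) or 4 (0.0697) or wild-type array 1 (0.0593) or 4 (0.209). It was also lost among genes above the median level (0.0677). Of 20 satellite cell and regeneration genes 1 was called higher, as over the list alone, the myogenic factor Myf6 (0.92, and 0.56 without wild-type arrays 2 and 3), with a camera adjusted p of 0.0487, 0.0537 with trisomic genes left out, and an adjusted p of 0.292 with an estimated correlation. The regeneration call was lost without any 1 array but Ts65Dn array 1 and wild-type array 2 (adjusted p from 0.0510 to 0.0835), without both wild-type arrays 2 and 3 (0.0582), and with level matching (0.0845). It was also lost with the replicate block (0.0630), median centring (0.0636) and genes above the median level (0.520). Of 23 neuromuscular junction genes 1 was called, Utrn, which encodes utrophin (0.89), with 3 higher and 1 lower over the list alone (camera adjusted p = 0.210). Of 17 clock genes 1 was called, Arntl, as over the list alone (camera adjusted p = 0.206).

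Markers of other cell types in the dissected muscle were measured as lists too. Of 18 endothelial genes 2 were called higher, the vascular growth factor receptor Kdr (0.99) and Emcn (1.18, and 0.73 without wild-type arrays 2 and 3), with 3 over the list alone (camera adjusted p = 0.0426, 0.0691 with trisomic genes left out, adjusted p = 0.367 with an estimated correlation). Of 12 fibroblast genes 1 was called, Pdgfra (0.62), as over the list alone (camera adjusted p = 0.0175, adjusted p = 0.348 with an estimated correlation). The endothelial call was lost without Ts65Dn array 1 (adjusted p = 0.160) or wild-type array 4 (0.130), and the fibroblast call with level matching (0.327) and quantile normalization (0.137). Among genes above the median level both calls were lost (0.480 and 0.509). Of 29 matrix genes 3 were called higher, Postn, Fn1 (1.11) and Bgn (1.23), with 4 higher and 3 lower over the list alone (camera adjusted p = 0.615). Of 25 macrophage and leukocyte genes 1 was called, Cd68 (camera adjusted p = 0.729), and of 14 adipocyte genes 1, Aqp7 (1.01; camera adjusted p = 0.908), each as over the list alone. Notch3, which fell by 0.48 (level-matched -0.21), was the 1 called gene of 12 smooth muscle and pericyte markers, with 1 higher and 2 lower over the list alone (camera adjusted p = 0.267). Tap1, which fell by 0.53 (level-matched -0.28), was the 1 called of 26 interferon-stimulated genes, with 0 over the list alone (camera adjusted p = 0.849). Of 11 Schwann cell genes 0 were called by limma over all genes and 2 were lower over the list alone, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.153, fry adjusted p = 0.0318). Of 10 tendon and 19 proliferation genes 0 were called by limma, over all genes or the list alone, with 1 and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.702 and 0.320). Of the erythroid list 3 genes were measured, too few for the list test, and 0 were called, with 0 at an unadjusted p under 0.05.

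Of the 29 lists tested, 16 were called by camera with the preset correlation of 0.01, 15 higher and 1 lower, the trisomic segments among them (adjusted p = 0.0137 for MMU16 and 0.0204 for MMU17). These directions are relative to the other genes, and the median log2 fold change over all genes was -0.10. Among genes above the median level, 2 of the 28 lists tested there were called, the sarcomere and MMU16 lists. With an estimated correlation 0 lists were called by camera, and the trisomic segments had an adjusted p of 0.196 and 0.231. Fry called 4 lists, the trisomic MMU16 and MMU17 segments among them (adjusted p = 0.0348 and 0.0318). The MMU17 camera call was lost with each array centred on its median (0.0549), with level matching (0.0746), and without wild-type array 1 (0.0549). It was also lost among genes above the median level (0.0825). Another split of the 8 arrays also called 16 lists. With cyclic loess 7 lists were called and with level matching 5, and the sarcomere, endothelial, immediate early and MMU16 lists stayed called in both, beside the respiratory chain list, which was called lower in both. The median and the direction given by camera differed in sign for the MMU16 segment and the adipocyte, macrophage, matrix, neuromuscular junction and respiratory chain lists, and for the MMU16, macrophage, matrix and neuromuscular junction lists the mean had the sign of the test.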

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

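The tests of wild-type arrays 2 and 3, of the level-dependent offset, of the clock genes and of Myh4 were chosen after the results were seen, and the counts over other splits of the arrays before.

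Each named gene and array measure was searched for an array far from the other 3 of its group. Of 342 such groups 14 stood out, and chance gives about 1 in 20. Wild-type array 3 held 5 of the 14: it was low for Ttc3 (7.47), Sesn1 (6.32), Hspb8 (8.59) and the mean of clock genes of the phase opposite to Arntl (6.04), and high for Fosb (4.66). Wild-type array 2 was low for Sim2 (6.02) and wild-type array 1 high for Tcf4 (7.50). Ts65Dn array 1 was high for the mean of the immediate early genes (5.82, and 5.84 with level matching), array 2 high for Tecrl (8.05) and low for Utrn (5.80), array 3 high for Rasef (6.19), and array 4 high for Postn (8.63) and Myh4 (10.5). Among the 13767 probe sets with no or several gene symbols, which the gene tests leave out, 1 passed a false discovery rate of 5% over all probe sets, and it was higher in Ts65Dn.

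The 1049 called genes were weighed against chance and against the state of the arrays. Of the 35 splits of the 8 arrays 1, the real one, called as many genes, and the highest other split called 1. This goes against chance assignment of arrays to groups for the count but does not exclude it, since 1 of 35 is the smallest share possible. At an unadjusted limma p under 0.05 the real split had 6948 genes and the highest other split 3158. Without wild-type arrays 2 and 3, where 1 other gene passed with 6 arrays, higher calls kept a median share of 0.80 (quartiles 0.70 and 0.93) of their log2 fold change. For lower calls the share was 0.78 (quartiles 0.71 and 0.86). A call needs a small spread within each group, and 1031 of the 1049 calls had groups that did not overlap. The selection thus favoured a high share, which cannot decide whether the narrow range of these arrays is the cause. Against level-matched genes the shares were 0.78 (quartiles 0.63 and 0.98) for higher and 0.60 (quartiles 0.52 and 0.74) for lower calls, and 96 of the calls passed. An offset that depends on level may thus make up part of the fold changes. The calls were picked for large fold changes, and the matching removes only the median offset at a level. These shares therefore cannot decide whether such an offset makes up the whole. A difference in array or RNA quality between all Ts65Dn and all wild-type arrays coincides with the groups and was not tested, and a biological difference stays open beside it.

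For the 16 called lists chance is not excluded, since 2 of the 35 splits called as many, the real one included, and the highest other split called 16. Splits that kept wild-type arrays 2 and 3 together called 6 to 16 lists and the others 0 to 7, which points to a structure of the arrays.

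In Ts65Dn array 4, Myh4, the fastest myosin heavy chain, lay 4.11 above the mean of the other Ts65Dn arrays and Actn3 2.37 above it. Fibres of a faster muscle in this sample are a possible explanation. The 12 other fast-fibre genes deviated by a median of -0.0257, but 11 of them were already bright in the other arrays, where a small share of such fibres would hardly show. The 1 with a low level, Mybpc2, lay 1.03 above the other arrays, which goes with such fibres, and Pvalb lay 0.71 above them, but 1 low gene is too few to decide, so such fibres cannot be told apart from a change within the soleus.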

How the results depend on the processing

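Cyclic loess, level matching, leaving out wild-type arrays 2 and 3 together and adjusting all probe sets together were chosen after the data were seen. Where no reason is given, the cause was not tested. The count of 1049 genes became 1 with quantile normalization, 436 among genes above the median level, 236 with array weights, 135 with cyclic loess (121 shared), 109 relative to level-matched genes (96 shared), 1 with both wild-type arrays left out, 1 with all probe sets adjusted together, and 4961 at an adjusted p under 0.10. Leaving out 1 array gave 0 to 2865 genes. It was 1008, 997, 891 and 889 with median centring, the mean of all probe sets, the genes outside the segments alone, and trend with robust estimation. The 16 lists became 2 among genes above the median level, 7 with cyclic loess, 5 relative to level-matched genes, 0 with an estimated correlation and 4 with fry, and were 11 to 16 under the others.

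The median of -0.0274 over the MMU16 genes turned positive with quantile normalization (0.0396), median centring (0.18), genes above the median level (0.53), array weights (0.000646), cyclic loess (0.0650), both wild-type arrays left out (0.0275), level matching (0.0741), the hand list (0.26) and the mean over members (0.15), and ranged from -0.0720 to 0.0161 without single arrays. The median over the MMU17 genes was 0.0449. It was positive in all alternatives run, from 0.0108 to 0.18 without single arrays (0.0108 without Ts65Dn array 3, 0.18 and 0.16 without wild-type arrays 2 and 3), and 0.16 without both wild-type arrays. There the difference in mean per array, 0.21, had an exact permutation p of 0.0667, the smallest that 6 arrays can give. The respiratory chain list, whose median was -0.0289 and whose direction by camera was higher without passing, was called lower with cyclic loess (-0.11), both wild-type arrays left out (-0.0980) and level matching (-0.0602). Its direction by camera was also lower, without passing, with quantile normalization, genes above the median level, array weights, and without wild-type array 2 or 3. The fatty acid list turned lower by camera, without passing, with cyclic loess (-0.0221) and level matching (0.0136 in the median), and its median, but not its direction by camera, was negative without both wild-type arrays (-0.0679). No called named gene turned its direction. Of the named genes' values under alternatives, 1880 kept their side of the threshold, 755 lost it, 47 newly passed and 14 uncalled ones changed sign.

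The labels give both groups the replicate numbers 1 to 4, without saying that a number pairs mice, so no pairing was used in the main test. Deviations of same-numbered arrays correlated by 0.03, 0.01, 0.09 and 0.07, and not every array correlated best with its own number. With 4 arrays per group these values do not exclude a pairing. With the replicate block the count of genes was 0 by limma, with 7014 at an unadjusted p under 0.05, and the MMU16 and MMU17 medians stayed at -0.0274 and 0.0449. The exact permutation p of the differences in mean per array, 0.15 and 0.22, was then 0.125, the smallest that 4 pairs can give. Low signal limits the comparison of dim genes: genes at a mean level of 5 or less had a median fold change of -0.22 outside the segments.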

Other observations

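The clock genes were grouped by phase, and this list and its tests were made after Arntl and Dbp had been seen. Besides Arntl, Cry1 (0.91), Nfil3 (0.60) and Clock (0.58) of the same phase had positive log2 fold changes, and Ciart (-1.15), Dbp (-0.68), Per2 (-0.36) and Per1 (-0.35) of the opposite phase negative ones. Nr1d1 (0.27), Hlf (0.19) and Bhlhe41 (0.32) of that phase had positive ones. None but Arntl passed the limma test. The difference between the phases was 1.16 higher in Ts65Dn (exact two-sided permutation p = 0.0857). It was 0.98 with level matching (exact permutation p = 0.0857), with 1 Ts65Dn array within the wild-type range, and 1.099 without wild-type arrays 2 and 3, so neither the offset nor these arrays are excluded as its source. Without Arntl and Dbp it was 0.85 (exact permutation p = 0.114), so a clock phase that differs between the groups may be present but cannot be told apart from chance here. Per the labels, all muscles were taken at about the same time of day.

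Pttg1, chosen after its values were seen, was at 9.24 to 9.40 in the 4 Ts65Dn arrays and at 9.66 in wild-type array 3, and at 6.83, 6.79 and 7.21 in wild-type arrays 1, 2 and 4 (limma adjusted p = 0.0653). Among chromosomes, the level-matched mean of genes above the median level differed most in the trisomic segments, by 0.41 and 0.39. The next were chromosomes X (0.17), 18 (0.14) and 3 (0.12), and the MMU16 genes outside the segment, at 0.10, ranked 8 of 22. The exact permutation p was 0.0286 for both segments and for all chromosomes compared but 4, 7, 11, 15 and 17.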
